A study of Mus musculus with 6 samples.

How the data were processed

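Total RNA of 6 samples of AML12 cells was sequenced, 3 labelled PA/OA and 3 labelled PP, each after 24 h. Per the labels' protocols, mRNA was obtained either with oligo(dT) beads or by removing rRNA, and libraries were made by a conventional or a strand-marking method; which was used is not given in the sources used here. The deposited table holds raw counts per gene, 1 column per library, which per the submitters' processing notes were made with featureCounts on build mm10; DESeq2 1.16.1 is also named there, without its role. The aligner, the annotation and the strand setting are not given in the sources used here. The counts were whole numbers with totals of 26825673, 26040579 and 24113169 for PA/OA replicates 1 to 3 and 27418502, 32560589 and 31832239 for PP replicates 1 to 3. Of 54532 genes in the table, 26561 had no count in any library. Symbols, biotypes and coordinates were taken from the table itself, and 105 symbols stood on more than 1 row, of which lists used the row with most counts. Among genes with 1 to 20 counts, 57.1% to 61.5% of counts were even, as would result if both mates of some read pairs were counted. Intervals on counts therefore cover counting error only, and may be too narrow.

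Groups were taken from the treatment labels and replicate numbers from the titles. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 15718, libraries were scaled with TMM, and PP was compared with PA/OA by the two-sided quasi-likelihood F-test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05. The log2 fold change is PP minus PA/OA, its SE was computed from the fold change and the F statistic, and CPM are TMM-scaled means with the SD over 3 libraries. A change of at least 2-fold means an absolute log2 fold change of 1 or more. Pairs of libraries within a group differed by more than sampling noise (chi-square per gene from 2.99 to 4.57 on halved counts), so each was counted as 1 replicate. Counts simulated at the library sizes of this comparison left 15516 genes tested. There edgeR recovered 58.0% of 100 genes changed by 0.5 and 90.3% of 93 genes changed by 1 on the log2 scale, with 5 false calls. The changes were set in both directions, at a common dispersion and without a trend with abundance. In the real data most genes changed and such a trend was present, so these rates do not carry over to them.

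Before the data were examined, 35 gene lists were written from general knowledge of lipid metabolism, stress, inflammation, growth and liver cell types, of which 33 with at least 5 measured members were tested with camera (limma 3.58.1), with an inter-gene correlation preset at 0.01, with the correlation estimated, and with fry. None of these lists was called with the estimated correlation. There camera tests with the degrees of freedom of the 6 libraries rather than of the genes, so a lost call need not reflect correlation. The percentile of a list's median was taken among random lists drawn from all genes tested and matched on abundance. Genes were named by rules fixed at the same time. These took the 8 protein-coding genes with the largest change in each direction (average log2 CPM of at least 1, groups not overlapping), the AMPK subunit, carboxylase and carnitine palmitoyltransferase genes, up to 4 members with the smallest p of each list described, and a set of genes of lipid handling and inflammation; some genes that these rules name are not reported here. Another annotated gene also lies over Srebf1, Ccl2, Acsl3, Me1, Acadl, Lpin2, Ndrg1, Slc2a1, Hk1, Aldoa, Atp5c1, Atp5d, mt-Nd1, mt-Nd2, mt-Nd4, Herpud1, Pdia6, Hsp90b1, Ftl1, Ephx1, Top2a, Ctsd, Rps28 and H1f0, so their counts are uncertain where reads of both strands were counted. Members that went against their list, where 5 or fewer, and Cd68, Malat1, Neat1, mt-Rnr1 and mt-Rnr2 were named after their values were seen, as were the genes of lists added later. Medians of lists and biotypes did not move, to 2 decimals, when genes with no count in a group were set at a floor of 3 counts over the group.

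Shares of counts were compared with an exact two-sided permutation test. Alternatives were size factors of DESeq2 1.42.0, library size only, upper-quartile scaling, no filter, at least 1 CPM in 3 libraries, the tools DESeq2 and limma-voom, the replicate number as a block, protein-coding genes only, leaving out each library in turn, and for shares the counts in protein-coding genes as denominator. Halved counts and removal of each library's lowess trend (span 0.4) with abundance, fitted over all genes tested, were added after seeing the data.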

Results

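RNA sequencing was carried out on AML12 cells, a mouse hepatocyte line kept in culture, after 24 h of treatment. The series title names an effect of Camellia oleifera meal peptides on lipid metabolism through the AMPK, ACC and CPT-1 pathway. The 6 libraries formed 2 groups of 3, one labelled PA/OA, the modelling reagent at 400 nM and 800 nM in the submitters' units, and one labelled PP, at 250 µg/ml. The labels name PP alone for the second group, and the design text leaves open whether those cells also received PA/OA. Untreated control cells were not analysed here. Total counts ran from 24113169 to 27418502 in 4 libraries, and were 31832239 and 32560589 in the other two, both PP. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

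The comparison of PP with PA/OA asks which genes differed in the cells labelled PP, and how the genes of the AMPK, ACC and CPT pathway stood. Cells labelled PP had more mRNA of the interferon-induced genes Cxcl10 and Rsad2, of the kinase gene Pim1, of Dbp, a transcription factor of the circadian clock, and of Plat, the tissue plasminogen activator. They had less of Has1, a hyaluronan synthase, and of Lrrc4, Gpr141 and Jrk. Plat rose from 57.5 ± 5.08 to 852 ± 58.1 CPM (SD, n = 3 in each group), and Pim1 from 10.6 ± 0.739 to 196 ± 5.22 CPM. Genes of cholesterol synthesis, glycolysis, lysosomes and mitosis were higher as groups, and 10 of 12 measured mitochondrially encoded mRNAs were lower. With an estimated correlation these groups were not called (adjusted p = 0.12 for cholesterol synthesis, glycolysis and lysosomes, 0.415 for mitosis and 0.281 for the mitochondrially encoded genes, by camera).

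Of 15718 genes tested, 11785 (75.0%) differed at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5510 higher and 6275 lower in PP. Of these, 5760 differed at least 2-fold, 1907 higher and 3853 lower. The values of the 3 PP and the 3 PA/OA libraries did not overlap for 12172 genes (77.4%), where chance gives 10%. The first principal component held 85.6% of the variance and parted the groups, and the biological coefficient of variation was 7.96%. The split by direction depended on the scaling. With library size only, the median of all genes fell by 0.44 on the log2 scale relative to TMM and the counts were 3235 higher and 8910 lower, and with upper-quartile scaling it fell by 0.24 and they were 4241 and 7688. Fold changes are given with TMM scaling, and list medians are also given relative to all genes, whose median log2 fold change was -0.09.

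**Figure D1:**
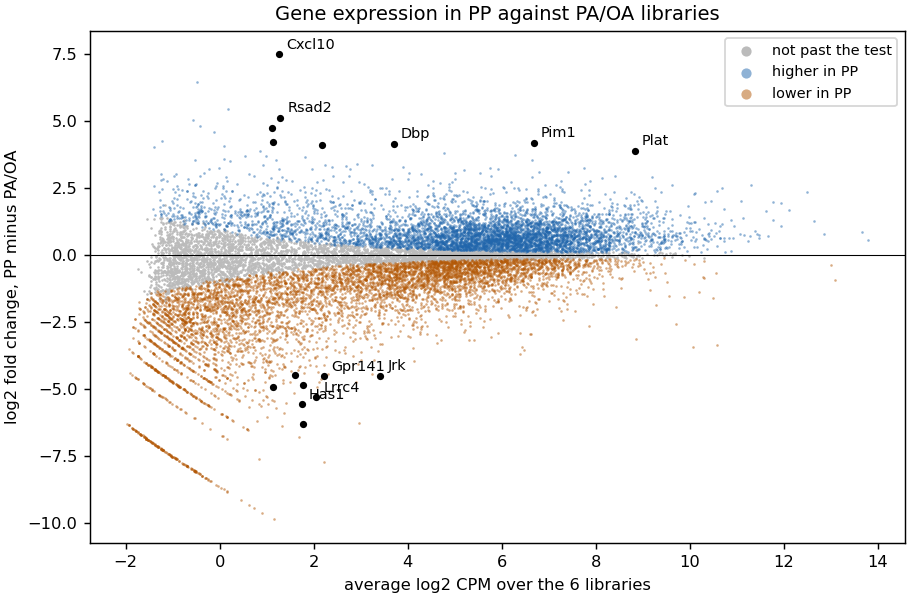
Each point is 1 of the 15718 genes tested, with its average log2 CPM over the 6 libraries on the x axis and its log2 fold change, PP minus PA/OA, on the y axis. Blue and brown points passed the edgeR test (5510 higher, 6275 lower), grey points did not, and black points are the genes named by size; the lowest diagonal stripe holds the 168 genes with no count in any PP library, whose fitted values are not bounds.

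Among protein-coding genes that passed the test with an average log2 CPM of at least 1, the largest rises were those of Cxcl10, Rsad2, D6Ertd527e, Rspo3, Pim1, Dbp, Rasgef1a and Plat, with log2 fold changes from 7.48 down to 3.89. Cxcl10 (chromosome 5, 92346638 to 92348889, build mm10) had 2 counts over the 3 PA/OA libraries and 382 over the PP libraries, a ratio of 160 by library totals, without TMM scaling, with an exact 95% interval from 44.0 to 1330 for counting error only. Without PA/OA replicate 3, the library that held those counts, the fitted log2 fold change of Cxcl10 went from 7.48 to 10.08. Rsad2 (chromosome 12, 26442746 to 26456452), which codes for the antiviral protein viperin, rose by 5.12 ± 0.38 (log2, SE; adjusted p = 5.94e-11, edgeR). Rspo3, which codes for an enhancer of WNT signalling, rose by 4.22 ± 0.40. Pim1 (chromosome 17, 29490812 to 29496111) rose by 4.20 ± 0.07 (adjusted p = 9.36e-21, edgeR), Dbp (chromosome 7, 45705088 to 45710203) by 4.15 ± 0.16 and Plat (chromosome 8, 22757727 to 22782844) by 3.89 ± 0.07. Rasgef1a rose by 4.09 ± 0.32, and by 4.74 without PA/OA replicate 2.

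The largest falls were those of 1700034J05Rik, Has1, Lrrc4, Mblac1, 9130023H24Rik, Gpr141, Jrk and Ovca2, with log2 fold changes from -6.30 to -4.48. Has1 (chromosome 17, 17843323 to 17855205) went from 6.20 ± 1.15 to 0.132 ± 0.127 CPM (SD, n = 3), and Jrk (chromosome 15, 74702301 to 74709535) from 19.8 ± 0.646 to 0.875 ± 0.0393 CPM. Most of these 8 genes held few counts in PP, so single libraries moved their values. The fitted change of Mblac1 was -4.91, and -6.59 without PP replicate 1 or -4.29 without PP replicate 2. That of Has1 was -5.56, and -6.31 without PP replicate 1 or -4.94 without PP replicate 3. Ovca2 stood at -5.58 without PP replicate 1, Lrrc4 at -5.96 without PP replicate 2 and 1700034J05Rik at -7.17 without PP replicate 3. The annotation places another gene over Cxcl10, Rspo3, Pim1, Dbp, Rasgef1a, 1700034J05Rik, Lrrc4, 9130023H24Rik, Gpr141, Jrk and Ovca2, and since no use of strand is given, their counts are uncertain.

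In the title's pathway, Acaca, the cytosolic acetyl-CoA carboxylase of fatty acid synthesis (chromosome 11, 84129672 to 84401651), was lower in PP and Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria (chromosome 19, 3323301 to 3385732), was higher. Acaca went from 167 ± 8.47 to 69.3 ± 1.25 CPM, a log2 fold change of -1.27 ± 0.06 (adjusted p = 1.47e-14, edgeR). Cpt1a went from 226 ± 13.9 to 312 ± 9.36 CPM, a log2 fold change of 0.47 ± 0.06 (adjusted p = 1.28e-07, edgeR). The AMPK regulatory subunit genes Prkab1 and Prkab2 rose by 0.76 and 1.43, and the catalytic subunit gene Prkaa2 by 0.97. The other catalytic subunit gene, Prkaa1, had a log2 fold change of -0.05 (adjusted p = 0.470, edgeR), and Prkag1 and Prkag2 had 0.16 and 0.06, none past the test. Acacb, the mitochondrial carboxylase, rose 2.23-fold from 1.04 to 2.33 CPM, Cpt2 rose by 0.37, and Cpt1b fell by 2.83 at under 1 CPM in both groups, or by 4.77 without PP replicate 2. Cpt1c held 9 counts or fewer in any library and was not tested. Only mRNA was measured, so the activity of AMPK and of these enzymes was not tested.

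The list of 17 measured AMPK, ACC and CPT1 pathway genes had 9 higher, 4 lower (Acaca, Cpt1b, Camkk2 and Slc25a20) and 4 not past the test, and adjusted over the list alone 9 higher and 5 lower. It was not called by camera (adjusted p = 0.695), and by the directional test of fry, which does not compare a list with other genes, the adjusted p was 0.00191; fry passed 17 of the 20 lists that camera did not call. Its median log2 fold change was 0.25 and its mean -0.01. The rise of Cpt1a was not called with library size only, where its log2 fold change was 0.03, and that of Cpt2 was lost there and with upper-quartile scaling. With library size only, Acacb did not pass (adjusted p = 0.0568, edgeR), Prkag1 was lower (-0.28, adjusted p = 0.0184, edgeR), the list had 5 higher and 8 lower, and Prkaa1 was lower there (-0.48) and with upper-quartile scaling (-0.29). With the trend of fold changes with abundance removed from each library, a setting chosen after seeing the data, the fold change of Cpt1a was -0.06 (adjusted p = 0.346, edgeR) and that of Cpt1b -1.39 (adjusted p = 0.122, edgeR), while Prkaa1 was lower (-0.41, adjusted p = 5.53e-06, edgeR) and Prkag1 (0.29, adjusted p = 0.0143) and Prkag2 (0.48, adjusted p = 0.0289) were higher. In the annotation another gene also lies over Acaca, Prkab1, Prkab2, Prkaa1, Prkag1, Prkag2, Acacb and Cpt1b, so their counts are uncertain too.

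**Figure D2:**
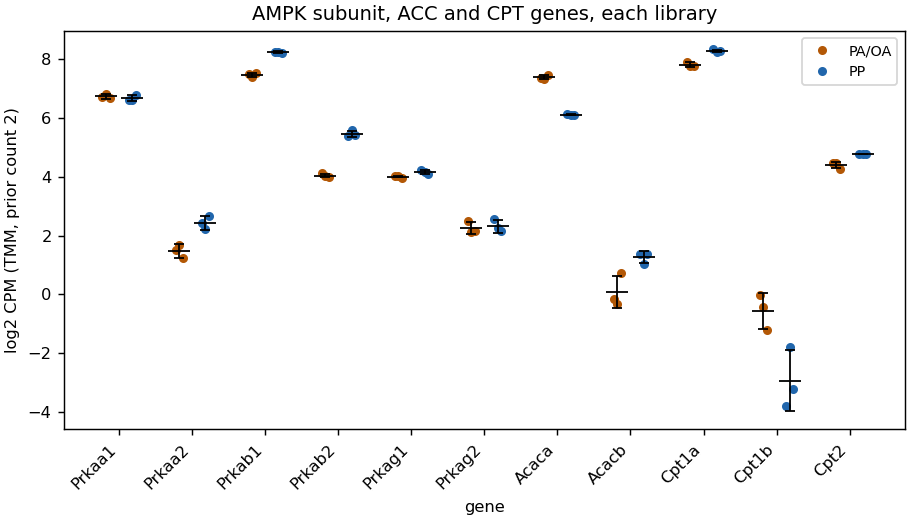
Log2 CPM (y axis, TMM scaling, prior count 2) of the AMPK subunit, acetyl-CoA carboxylase and carnitine palmitoyltransferase genes (x axis) in each of the 3 PA/OA and 3 PP libraries; points are libraries, horizontal marks are means and bars are 1 SD. Acaca was lower in all PP libraries (mean 69.3 against 167 CPM), Prkab1, Prkab2 and Cpt1a were higher, and Prkaa1, Prkag1 and Prkag2 did not pass the edgeR test, with log2 fold changes of -0.05, 0.16 and 0.06.

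Cholesterol synthesis genes were higher in PP. Of 26 measured, 21 rose, 2 fell, among them Hsd17b7 by 0.46, and 3 did not pass, with a median log2 fold change of 1.08, or 1.17 relative to all genes (camera adjusted p = 2.13e-11, and adjusted p = 0.12 with an estimated correlation). Insig1, which holds the sterol sensor in the endoplasmic reticulum, rose 8.66-fold from 35.3 ± 0.677 to 305 ± 17.9 CPM. Msmo1 rose by 1.73 and Fdft1 by 1.72. Fatty acid synthesis genes went both ways. Of 17 measured, 12 rose and 5 fell, with a median of 0.79, or 0.88 relative to all genes (camera adjusted p = 0.00883, and adjusted p = 0.186 with an estimated correlation). The stearoyl-CoA desaturase gene Scd1 rose from 437 ± 12.7 to 1559 ± 46.1 CPM, Acsl3 rose by 1.52, Slc25a1 by 1.72, Me1 by 1.21 and Srebf1 by 0.79. Fasn, the fatty acid synthase gene, fell from 272 ± 29.7 to 110 ± 4.68 CPM, Elovl6 fell by 1.46, Acsl5 by 1.17, Acly by 0.43 and Elovl1 by 0.36.

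Of 28 measured genes of PPAR targets and fatty acid oxidation, 19 rose, 7 fell and 2 did not pass, with a median of 0.59, or 0.68 relative to all genes (camera adjusted p = 0.00311, and adjusted p = 0.138 with an estimated correlation). The acyl-CoA thioesterase gene Acot1 rose by 1.59, the dehydrogenase genes Acadl and Hadh by 1.31 and 1.00, the fatty acid transporter gene Cd36 by 1.61 and the transcription factor gene Creb3l3 by 3.40. Pdk4 rose by 1.42, but was not past the test without PP replicate 1 (1.03, adjusted p = 0.0737, edgeR) or with library size only. Angptl4, an inhibitor of lipoprotein lipase, fell by 1.02. Ppara had a log2 fold change of 0.18 (adjusted p = 0.0855, edgeR), and passed with 0.30 without PP replicate 2, but as lower with library size only (-0.25, adjusted p = 0.0218, edgeR). Of 17 measured lipid droplet and triglyceride genes, 9 rose and 5 fell (G0s2, Fitm2, Plin4, Gpam and Lipe), with a median of 0.52, or 0.61 relative to all genes (camera adjusted p = 0.00311, and adjusted p = 0.376 with an estimated correlation). The lipin genes Lpin1 and Lpin2 rose 5.67-fold and 7.34-fold, Hilpda by 1.86 on the log2 scale, the triglyceride lipase gene Pnpla2 by 1.46 and Plin2, which coats lipid droplets, by 0.91. G0s2, which codes for an inhibitor of the lipase made by Pnpla2, fell by 2.03. Fatty acid synthesis was not called with library size only (adjusted p = 0.0969) or among protein-coding genes alone (0.0657), and lipid droplets were not called with limma-voom (0.125). Lipid droplet genes had 6 higher and 7 lower with library size only, with a median of 0.09, and there 14 of the PPAR list were higher and 9 lower, with a median of 0.16.

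Of 24 measured genes of glycolysis and hypoxia, 21 rose, 1 fell (Slc16a3, a lactate transporter gene, by 4.17) and 2 did not pass, with a median of 1.52, or 1.60 relative to all genes (camera adjusted p = 1.32e-21, and adjusted p = 0.12 with an estimated correlation). The glucose transporter gene Slc2a1 rose from 201 ± 4.84 to 811 ± 16.7 CPM, Ndrg1 from 704 ± 34.7 to 4315 ± 143 CPM, the hexokinase gene Hk1 by 2.01 and the aldolase gene Aldoa by 1.94. Of 34 measured autophagy and lysosome genes, 31 rose and 2 fell (Wipi2 and Becn1, which act in the formation of autophagosomes), or 32 and 2 adjusted over the list alone. The median was 1.09, or 1.18 relative to all genes (camera adjusted p = 2.67e-15, and adjusted p = 0.12 with an estimated correlation). The sialidase gene Neu1 rose by 2.29, the proton pump gene Atp6v0d1 by 2.00 and the cathepsin genes Ctsb and Ctsd by 1.61 and 1.72; Ctsb and Fdft1 overlap in the annotation. Of 32 measured G2/M genes, 29 rose, 1 fell (Kif20a by 0.34) and 2 did not pass, with a median of 0.89, or 0.97 relative to all genes (camera adjusted p = 3.17e-06, and adjusted p = 0.415 with an estimated correlation). Bub1 rose by 2.41, the mitotic kinase gene Aurkb by 2.08, Dlgap5 by 1.62 and the topoisomerase gene Top2a by 1.18. Of 32 measured G1/S genes, 16 rose and 6 fell (15 and 6 adjusted over the list alone), and that list was not called (adjusted p = 0.394); with library size only 9 were higher and 13 lower, with a median of -0.15.

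Most mitochondrially encoded mRNAs were lower in PP, but the most abundant one was higher. Of 12 measured, 10 fell, 1 rose (mt-Co1, by 0.85, from 9317 ± 872 to 16780 ± 463 CPM) and 1 did not pass, or 10 fell and 2 rose adjusted over the list alone. The median was -1.49, or -1.40 relative to all genes (camera adjusted p = 6.81e-08, and adjusted p = 0.281 with an estimated correlation). The respiratory complex I genes mt-Nd1 and mt-Nd2 fell from 1437 ± 130 to 241 ± 21.3 CPM and from 828 ± 46.5 to 95.1 ± 7.42 CPM, mt-Nd4 fell by 1.85 and mt-Cytb by 1.60. Summed over the 12 genes, CPM with TMM scaling went from 16790 ± 1350 to 18950 ± 419, and without mt-Co1 from 7471 ± 477 to 2171 ± 139. Of library totals, genes of the mitochondrial genome, rRNA included, took 1.96% in PA/OA and 1.68% in PP. The direction of the sum thus depended on the scaling. The mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2, which are not in the list, rose by 3.25 and 1.79. Reads of these genes can be shared with nuclear copies, so their counts are uncertain. Of 39 nuclear genes of the respiratory chain, 29 rose, 2 fell (Ndufa9 and Cycs) and 8 did not pass, with a median of 0.41, or 0.49 relative to all genes (camera adjusted p = 0.00272, and adjusted p = 0.424 with an estimated correlation). Atp5c1 rose by 0.98, Cox8a by 0.96, Uqcrfs1 by 0.95 and Atp5d by 0.94. With library size only, 12 of these 39 were higher and 14 lower, their median was -0.03, and the list was not called (adjusted p = 0.0971).

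Of 23 unfolded protein response genes, 18 rose and 2 fell (Selenos and Derl3), with a median of 0.49, or 0.58 relative to all genes (camera adjusted p = 0.000176, and adjusted p = 0.281 with an estimated correlation). Herpud1 rose by 1.81, and the chaperone genes Calr, Pdia6 and Hsp90b1 by 1.34, 1.30 and 1.40. Of these, 10 were higher and 8 lower with library size only, with a median of 0.06. Of 30 NRF2 and antioxidant genes, 20 rose and 3 fell (Gsr, Srxn1 and Gsta3), with a median of 0.46, or 0.54 relative to all genes (camera adjusted p = 2.27e-06, and adjusted p = 0.12 with an estimated correlation). The ferritin gene Ftl1 rose by 2.40, the heme oxygenase gene Hmox1 by 2.03, Ephx1 by 1.64 and the catalase gene Cat by 1.47. The NRF2 list had 14 higher and 9 lower with library size only, with a median of 0.02. Of 78 cytosolic ribosomal protein genes, 73 rose and 1 fell (Rpl21), or 75 and 1 adjusted over the list alone, with a median of 0.66, or 0.75 relative to all genes (camera adjusted p = 1.44e-11, and adjusted p = 0.413 with an estimated correlation). Rpl37a rose by 1.28, Rps28 by 1.07, Rps26 by 0.89 and Rpl9 by 0.84. Such genes share reads with their pseudogenes. With library size only, 56 ribosomal protein genes were higher and 3 lower, with a median of 0.23. Of 16 histone genes, 9 rose and 2 fell (Hist1h1e and Hist2h4), with a median of 1.05, or 1.14 relative to all genes (camera adjusted p = 0.0351, and adjusted p = 0.281 with an estimated correlation). Hist1h1c rose 5.77-fold, Hist1h2bc 5.68-fold, Hist1h2bg 6.01-fold and H1f0, a linker histone gene that is also expressed outside S phase, 2.16-fold. The histone call was lost without any 1 of the 6 libraries, with adjusted p from 0.0591 to 0.0926, and with limma-voom (0.0772), no filter (0.233) or protein-coding genes alone (0.0748).

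**Figure D3:**
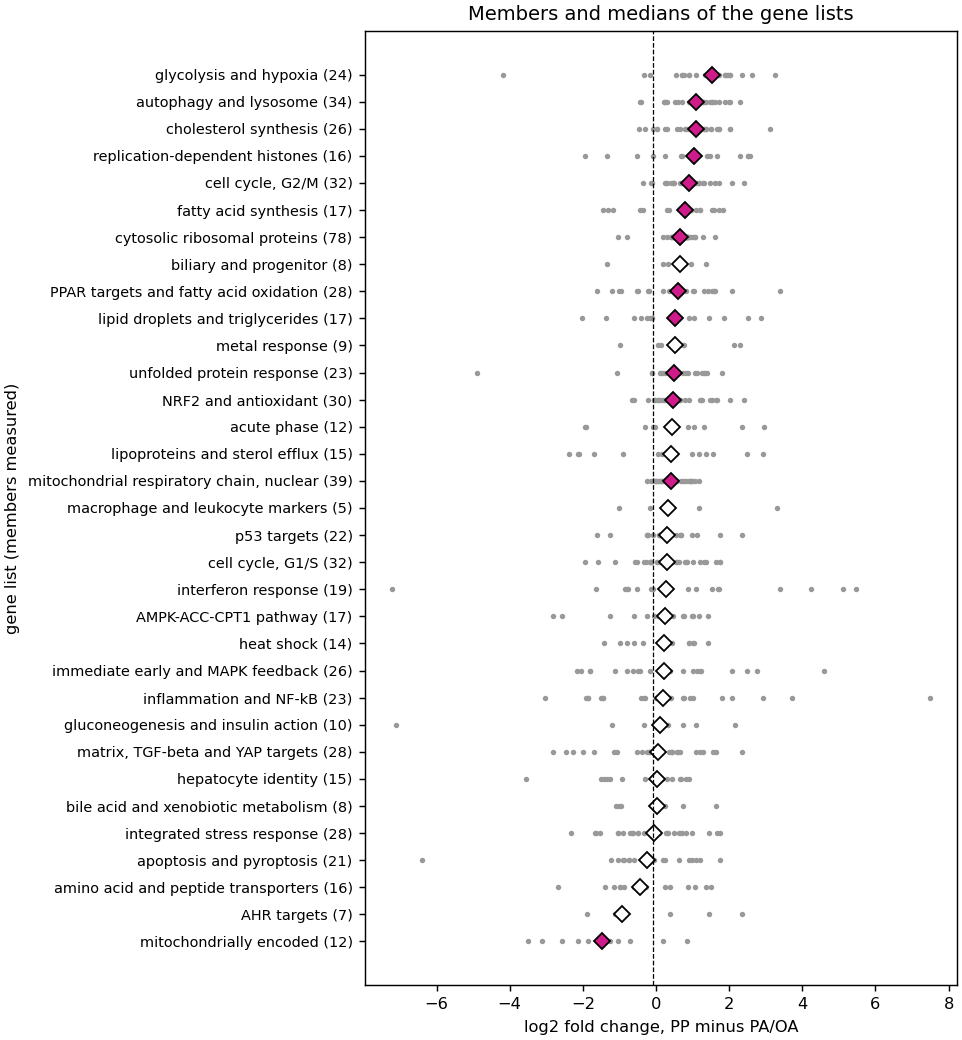
Log2 fold change, PP minus PA/OA (x axis), of each measured member (grey points) and of the median (diamonds) of the 33 lists tested (y axis, number of members measured in parentheses); filled diamonds are lists past an adjusted p of 0.05 by camera and the dashed line is the median of all genes, -0.09. Glycolysis and hypoxia had the highest median, 1.52, and the mitochondrially encoded genes the lowest, -1.49, under TMM; with library size only the median of the nuclear respiratory chain genes falls below 0, to -0.03, and Slc2a2 and Dhx58, the points farthest to the left, had no count in PP, so their fitted values are not bounds.

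Besides the AMPK list, 19 of the 33 lists tested were not called by camera, and in each of them members went both ways. Of inflammation and NF-kB genes, 11 were higher and 9 lower (adjusted p = 0.889), with the chemokine gene Ccl2 up from 9.20 ± 0.606 to 38.8 ± 0.967 CPM; Il6 held 2 counts in 1 library and none in the others and was not tested. Of interferon response genes, 9 were higher and 5 lower (adjusted p = 0.254; 0.0364 with the abundance trend removed), and of acute phase genes 7 and 3 (0.254). Integrated stress response genes had 12 higher and 14 lower (0.394), heat shock 8 and 5 (0.254), amino acid and peptide transporters 5 and 9 (0.141), metal response 6 and 1 (0.0866; 7 and 1 adjusted over the list alone) and immediate early genes 13 and 9 (0.212; 14 and 9). Lipoproteins and sterol efflux had 6 higher and 5 lower (0.229), gluconeogenesis and insulin action 4 and 3 (0.254), AHR targets 3 and 4 (0.278), and bile acid and xenobiotic metabolism 2 and 2 (0.889). p53 targets had 11 higher and 5 lower (0.0588), and passed in 5 of the 6 fits that left out 1 library, with adjusted p from 0.0335 to 0.0458, but not without PA/OA replicate 1. By camera, p53 targets (adjusted p = 0.00266), metal response (0.00979) and immediate early genes (0.0317) were called with no filter, biliary and progenitor genes (0.0284) with limma-voom, and the integrated stress response (0.0136) with library size only. The larger side of several of these lists turned with library size only, to 7 higher and 10 lower for p53 targets, 5 and 8 for heat shock, 9 and 14 for immediate early genes, 8 and 11 for inflammation and NF-kB, and 3 and 6 for gluconeogenesis and insulin action. There the integrated stress response had 8 higher and 19 lower, hepatocyte identity 2 and 9, bile acid and xenobiotic metabolism 1 and 6, matrix genes 9 and 12, and acute phase genes 5 and 5. Apoptosis and pyroptosis had 6 higher and 10 lower (0.971; 8 and 10 adjusted over the list alone), and matrix, TGF-beta and YAP targets 11 and 11 (0.636). Of the cell type lists, hepatocyte identity had 6 higher and 6 lower (0.889; 6 and 7 adjusted over the list alone), biliary and progenitor genes 7 and 1 (0.0839), and macrophage and leukocyte markers 2 and 1 of 5 measured (0.636), with Cd68, which lysosomes also hold, up by 3.30. Endothelial markers, with 3 measured, and stellate cell markers, with 2, were too few to test and each had 1 gene lower. The other lists had equal counts adjusted over the list alone. Among the 20 lists not called, median, mean and camera direction differed in sign for the AMPK list (0.25, -0.01, up), gluconeogenesis (0.11, -0.40, up), AHR targets (-0.93, -0.12, up), bile acid (0.03, -0.05, down), hepatocyte identity (0.03, -0.42, down) and matrix genes (0.06, -0.09, up).

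The libraries also differed in what they were made of. Genes with at least 1 count numbered 23051 ± 266 in PA/OA and 19673 ± 113 in PP (SD, n = 3). Of all counts, lincRNA genes took 2.18% ± 0.119 in PA/OA and 0.728% ± 0.0389 in PP, among them Malat1 with 1.32% and 0.518% and Neat1 with 0.227% and 0.0155%, both nuclear RNAs. Antisense genes took 0.201% and 0.0889%, sense intronic genes 0.0316% and 0.0125%, genes marked TEC, models that still await experimental evidence, 0.255% and 0.115%, and rRNA genes, mitochondrial rRNA included, 0.173% and 0.0886%. Within that last class mt-Rnr1 and mt-Rnr2 rose, by 3.25 and 1.79 on the log2 scale, so the summed share of the other rRNA genes fell further than that of the class. Gene by gene this did not hold for most: of 7 such genes tested, 3 were lower, 0 higher and 4 not past the test, with a median log2 fold change of 0.65. Genes of the mitochondrial genome, rRNA included, took 1.96% ± 0.147 and 1.68% ± 0.0284 of library totals, cytosolic ribosomal protein genes 5.43% ± 0.176 and 6.38% ± 0.240, histone genes 0.0417% and 0.0814% (of this H1f0 0.0331% and 0.053%, and Hist1h1c 0.00521% and 0.0222%), the 10 most abundant genes 7.03% and 8.004%, and protein-coding genes 95.04% and 96.57%. Each of these 13 differences had an exact two-sided permutation p of 0.1 (0.1 after Benjamini-Hochberg adjustment), the smallest that 3 libraries against 3 allow. By gene, 642 of 863 tested TEC genes, 361 of 626 antisense genes and 257 of 459 lincRNA genes were lower in PP, against 4346 of 11873 protein-coding genes. The median log2 fold change of protein-coding genes ran from -0.92 in the lowest of 8 bins of abundance to 0.56 in the highest. A trend with abundance over all genes tested, non-coding genes included, was then removed from each library. There fatty acid synthesis, ribosomal proteins (both adjusted p = 0.792 by camera), the nuclear respiratory chain (0.514), the unfolded protein response and NRF2 genes (both 0.0842) were not called. Interferon response genes, with a relative median of 1.28 in place of 0.36 (0.0364 by camera), and the integrated stress response, with -0.63 in place of 0.03 (4.48e-07), were called.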

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

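Halved counts and the removal of the abundance trend were chosen only after the data were seen. The replicate numbers did not pair the libraries (correlations of deviations from -0.026 to 0.022), and with the replicate block 11515 genes changed, 11473 of them among the 11785; not every library correlated best with its own number. Over the other alternatives the count of changed genes ran from 9307 (protein-coding genes only, 11873 tested) to 12979 (no filter, 27971 tested), and without each library in turn from 11374 to 11934. Library size only gave 3235 higher genes, and protein-coding genes only gave 3608 changed at least 2-fold, where fewer genes were tested; in the former the median of all genes shifted. With the correlation estimated, each of the 13 called lists lost its call at the same relative median: cholesterol synthesis 1.17, glycolysis 1.60, lysosome 1.18, NRF2 0.54, PPAR targets 0.68, fatty acid synthesis 0.88, lipid droplets 0.61, nuclear respiratory chain 0.49, mitochondrially encoded -1.40, unfolded protein response 0.58, G2/M 0.97, ribosomal proteins 0.75 and histones 1.14. PPAR targets and fatty acid synthesis lost theirs at estimated correlations of -0.029 and -0.018, below the preset 0.01. Correlation therefore cannot account for the loss of their calls. Fry passed 17 of the 20 lists that camera did not call, the AMPK list (relative median 0.34) among them. Calls were gained with no filter by p53 targets (0.70), metal response (0.93) and immediate early genes (0.64), with limma-voom by biliary genes (0.73) and with library size only by the integrated stress response (0.03). Calls were lost with library size only by fatty acid synthesis (0.88) and the respiratory chain (0.49), with limma-voom by lipid droplets (0.61) and histones (1.12), with no filter by histones (0.60), and with protein-coding genes only by fatty acid synthesis (0.75) and histones (1.01). Histones lost theirs without any 1 library, at 0.82 to 1.03. With the abundance trend removed, which takes out what follows abundance, calls ended for NRF2 (0.10), ribosomal proteins (0.003), fatty acid synthesis (0.11), the respiratory chain (0.15) and the unfolded protein response (0.30), and signs turned for Cpt1a (-0.059), gluconeogenesis (-0.26), heat shock (-0.29), hepatocyte identity (-0.072), immediate early genes (-0.004) and the integrated stress response (-0.63, then called), while interferon genes (1.28, from 0.36) gained a call. Signs also turned elsewhere, and the cause was not tested. With library size only these were Cpt2 (-0.061) and Prkag2 (-0.38), and, past the test as lower, Ppara (-0.25) and Prkag1 (-0.28), and with upper-quartile scaling Ppara (-0.058), Prkag1 (-0.08) and Prkag2 (-0.18). With no filter they were apoptosis (0.10) and bile acid genes (-0.55), and with protein-coding genes only Prkag2 (-0.027), bile acid genes (-0.010), hepatocyte identity (-0.011) and the integrated stress response (-0.10). That last list also turned at 1 CPM in 3 libraries (-0.075) and with halved counts (-0.04). Without each library in turn, the ranges crossed 0 for the integrated stress response (-0.072 to 0.034), hepatocyte identity (-0.029 to 0.124), matrix genes (-0.001 to 0.26), Prkag2 (-0.051 to 0.19) and Prkaa1 (-0.087 to 0.001). Protein-coding genes as the denominator make their own share 100% by construction, a difference of 0. Genes under about 1 CPM held too few counts to place a fold closely.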

Other observations

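The tests on sequencing depth, genomic DNA, the abundance trend, even counts, ribosome production, clock genes and zinc-finger genes were chosen only after the results were seen; those on unspliced RNA and on other splits of the libraries were set before.

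Most measured genes of ribosome assembly and RNA polymerase I were lower in PP. The genes of the cytosolic ribosomal proteins went the other way with TMM scaling, 73 of 78 higher and 1 lower. Rrp12 and Mdn1, both needed for ribosome assembly, fell by 3.70 ± 0.10 and 3.54 ± 0.08 on the log2 scale (SE), and raised the hypothesis that ribosome production genes were lower in PP as a group. Of 48 other measured genes of ribosome assembly and RNA polymerase I, 39 fell, 4 rose (Polr1c, Nvl, Ncl and Utp15) and the rest did not pass, with a median of -1.13 relative to all genes (camera adjusted p = 5.88e-22, and adjusted p = 0.0324 with an estimated correlation). Here and for the clock and zinc-finger genes, p was adjusted over the 4 lists added after the results were seen, not over the 33 planned ones. These adjusted p-values therefore cannot be set beside those of the planned lists. Dkc1 fell by 3.15, Ftsj3 by 2.94, Bop1 by 2.89, Nop56 by 2.65 and the polymerase I subunit gene Polr1a by 1.77. With the abundance trend over all genes tested removed, the relative median was -1.40, so that trend does not account for the fall. With library size only 46 fell and 1 rose. Myc, a known activator of such genes, fell by 0.44, and Mxd1 and Mxi1, which code for proteins that compete with MYC for its partner MAX, rose by 2.73 and 1.81. These 3 were picked after their values were seen, and a part of MYC in the fall was not tested.

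Clock and zinc-finger genes also moved. Beside Dbp, the clock output genes Nr1d1 and Tef rose by 3.75 ± 0.09 and 3.21 ± 0.07, and 6 of 7 others measured rose, among them Per1 by 2.96 and Per3 by 2.39, while Ciart fell by 0.81 (camera adjusted p = 5.80e-08, and adjusted p = 0.0442 with an estimated correlation). The hypothesis of an opposite clock phase, as it was set, called for Arntl, Npas2, Clock and Nfil3 to be lower. Of these 4, 3 were measured, without Npas2, and Arntl, Clock and Nfil3 rose by 0.36, 0.13 and 1.22. With library size only Arntl was at -0.08, Clock fell by 0.30 and Nfil3 rose by 0.79. The test thus remains undecided for Arntl and Clock, and Nfil3 went against the hypothesis under each of the 4 scalings. Of 294 genes named Zfp with a number, 172 fell and 61 rose, with a median of -0.67 (camera adjusted p = 0.000389, but adjusted p = 0.116 with an estimated correlation). Those among the largest falls prompted the hypothesis that zinc-finger genes were lower as a group, so these p-values, which include them, do not test it. The 200 largest falls were taken among protein-coding genes with an average log2 CPM of at least 1, and held 23 zinc-finger genes. Without these 23, 149 fell and 61 rose, and less abundant zinc-finger genes stayed in. The median of the rest, -0.60, still lay at percentile 0 of random lists matched on abundance, as the hypothesis predicts.

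Low-abundance and non-coding genes were lower in PP. Sequencing depth is argued against: after thinning all libraries to the smallest total, the lowest PA/OA library still detected 3283 genes more than the highest PP library. Genomic DNA in the PA/OA libraries as the whole cause is argued against for non-coding genes and tested low-abundance genes: the share of 1499 olfactory, vomeronasal and taste receptor genes was lower in PP (log2 ratio -1.33, 95% interval -1.49 to -1.18), but the CPM per kb lost over them was 1.51% of that lost over all 3160 TEC genes and 2.11% (95% bootstrap interval 1.03 to 3.50) of that lost over the lowest bin of protein-coding genes tested, the highest figure of the 5 classes compared. It stays open for the 8684 other protein-coding genes that were too low to be tested, where the figure was 40.4% (19.8 to 69.0), as does more unspliced nuclear RNA in PA/OA, since TEC genes inside protein-coding genes were lower than those outside by a matched difference of -0.39, with a 95% bootstrap interval from -0.77 to 0.25, too wide to decide. A change in nuclear RNA with the treatment, such as the fall of Neat1 by 3.43, was not tested apart from the group and stays open too.

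Fold changes of protein-coding genes went with abundance. A trend with abundance over all genes tested as the whole cause is argued against for 7 lists (cholesterol synthesis, PPAR targets, glycolysis, mitochondrially encoded, G2/M, lysosome and histones). These lists stayed past the threshold with that trend removed and lay outside the central 95% of matched random lists. The trend and the random lists were both taken over all genes tested, non-coding genes included. A trend among protein-coding genes alone was not tested. Mitochondrially encoded genes and histones went further from 0, from -1.40 to -1.93 and from 1.14 to 1.94. The others shrank: glycolysis from 1.60 to 0.70, PPAR targets from 0.68 to 0.28, cholesterol synthesis from 1.17 to 0.73, lysosome from 1.18 to 0.81 and G2/M from 0.97 to 0.80. With the trend left in, the histone call was lost without any 1 library, and among protein-coding genes only (adjusted p = 0.0748 by camera). For the 5 lists whose calls ended, the trend as the whole cause stays open, since they were picked by that loss and lay on both sides: the respiratory chain, unfolded protein response, NRF2 and ribosomal proteins, 4 of the 5, lay within matched random lists (percentiles 68.6, 72.9, 53.5 and 97.0) and fatty acid synthesis outside (98.1), while their relative medians went from 0.49, 0.58, 0.54, 0.75 and 0.88 to 0.15, 0.30, 0.10, 0.003 and 0.11. Lipid droplet genes were still called (0.53), but lay within, at percentile 92.3. The integrated stress response, not called with the trend left in, was called as lower once it was removed (-0.63, adjusted p = 4.48e-07 by camera). An effect of the treatment on the 7 lists remains a hypothesis, and a library batch that follows the groups was not tested.

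Low counts were even more often than odd, from 57.1% to 61.5% of genes with 1 to 20 counts over the 6 libraries. Read pairs of which both mates were counted, as 2 reads, may explain this, since single reads would give about equal shares. The many odd counts show that not every pair added 2 to its gene. With counts halved, 10984 genes of 13991 tested changed, 10729 of them among the 11785. No biological explanation was tested.

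Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 11785 changed genes, 5760 changed at least 2-fold and 13 called lists; the highest of the others gave 0, 0 and 10. With 10 splits the share is never under 0.05. By edgeR, the other splits had 16 to 28 genes at an unadjusted p under 0.05, against 12032 in the real one, and no other test of single genes was run on them. The other splits still called 8 to 10 lists by camera. Each of them set 2 libraries of one group with 1 of the other on each side, so the group difference entered the spread within sides. Few called genes there were thus fixed in advance, and the splits cannot decide whether the grouping arose by chance.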
